A study of Mus musculus with 12 samples.

How the data were processed

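Total RNA was taken from formalin-fixed, paraffin-embedded mouse brain tissue with a RecoverAll kit, per the labels' protocols, and sequenced as 12 libraries, 3 in each of 4 groups given by the tumour genotype in the labels: IDH1_R132H, IDH1WT, PDGFA and normal brain. Libraries of a group are numbered 1 to 3 in the order of their records; the numbers only name a library and pair nothing. The deposited count table holds raw read counts per gene for 49671 Ensembl genes. Per the submitters' processing notes, reads were handled with STAR 2.5.2b, Subread, featureCounts 1.5.1 and DESeq2 1.16.1 on GRCm38. The gene annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes such as Dlx6os1 cannot be told apart, and genes with near-identical copies (H2-K1 and H2-D1, Rps3a1 and Rps3a3, the haemoglobin genes) are uncertain. A second deposited table holds log2 values for 23792 genes, regularized log (rlog) values by the table's own name, and was used only as an alternative. Its values had a median correlation across genes of 0.99 with log2 CPM computed from the counts (lowest library 0.986), over 17779 genes. Every column was matched to a sample by name.

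Gene symbols and coordinates were taken from GENCODE release M21 on GRCm38, which named 49326 of the 49671 genes; 42503 genes had a count in at least 1 library. Analyses were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept with filterByExpr (minimum count 10, minimum total 15), leaving 17812, and libraries were scaled with TMM factors. TMM sets the median gene to no change, so a shift shared by most genes would not be seen. A quasi-likelihood model with robust dispersion and 1 coefficient per group was fitted to the 12 libraries, leaving 8 residual degrees of freedom. It gave 8 comparisons: tumours against normal brain (the 3 tumour groups weighted equally), IDH1_R132H against the equally weighted IDH1WT and PDGFA groups, each pair of tumour groups, and each tumour group against normal brain. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 with no fold change minimum. Adjusted p-values given for genes are from edgeR unless another tool is named. The common biological coefficient of variation was 26.5%, and the median standard error of a log2 fold change was 0.23 for tumours against normal brain and 0.286 for IDH1_R132H against IDH1WT, which sets the size of difference that could be called.

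Lists of genes were fixed before the data were examined: 4 glioma subtype lists, 11 cell type lists and 13 pathway lists, written from general knowledge, each with at least 5 tested members. They were tested with camera at a preset correlation between genes of 0.01, adjusted over the 28 lists, with an estimated correlation and the rotation test fry as alternatives. Subtype scores are the mean over a list of log2 CPM (prior count 2) less each gene's mean over the 12 libraries, compared by an exact two-sided permutation test. Principal components were taken over the 2000 most variable genes.

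Genes named in the text follow a rule fixed before the data were examined. For tumours against normal brain, IDH1_R132H against other tumours and IDH1_R132H against IDH1WT it takes the 10 called genes with the largest change each way that have a mean log2 CPM of at least 3, groups that do not overlap and an approved-style symbol, and for the other comparisons the first 3 each way. It adds the 4 members of each described list with the smallest p, and 13 genes in every case, among them Idh1, Pdgfa, Cdkn2a, Atrx, Pdgfra, Egfr, Olig2, Gfap, Cd44, Nf1, Trp53 and Mki67. A few genes that the rule takes are not reported here. Gfra2, Stk32b, Fndc9, Rps3a1, Rps3a3, Gpatch4, Apold1, A830036E02Rik, Nlrp5-ps, the genes called by DESeq2 between tumour groups and the genes named in the closing section outside this rule were chosen after their values were seen.

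The procedure was tested on simulated counts with 200 genes changed by known factors. Each gene was drawn independently with its fitted dispersion, and the libraries of a group shared a mean. A shift of many genes together in a single library was not simulated, so recovery and false calls may differ in these data. For tumours against normal brain edgeR, run on 17036 genes, recovered 41.8%, 77.6% and 86.4% of genes changed 2-fold, 4-fold and 8-fold with 5 false calls, and DESeq2 50.7%, 83.6% and 90.9% with 26. DESeq2 was run on 17812 genes in each simulation. For IDH1_R132H against other tumours edgeR, on 17383 genes, recovered 35.8%, 80.6% and 86.4% with 8 false calls, and DESeq2 58.2%, 85.1% and 86.4% with 31. For IDH1_R132H against IDH1WT edgeR, on 17462 genes, recovered 34.3%, 65.7% and 95.5% with 6 false calls, and DESeq2 47.8%, 77.6% and 95.5% with 24.

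Alternatives planned before the data were examined were RLE size factors, DESeq2, limma on the deposited log2 values, limma voom with sample quality weights, no low count filter, a stricter filter, a fit of the compared groups alone, the level of neuron markers as a covariate, a log2 fold change minimum of 1, and leaving out each library in turn. Added after the data were seen were the removal of IDH1_R132H tumour 3 and PDGFA tumour 1 together, the removal of ribosomal-RNA-like loci, and animal sex read from Xist and Ddx3y as a covariate, by which 2 libraries had more Xist and 10 more Ddx3y. Viral transcripts, exon-level counts and sequence variants were not analysed here.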

Results

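RNA was sequenced from 12 formalin-fixed, paraffin-embedded mouse brain samples, 9 brain tumours and 3 normal brains. The tumours fall into 3 groups of 3 by the tumour genotype in the labels. IDH1_R132H names the mutant isocitrate dehydrogenase 1 common in human diffuse glioma, IDH1WT the wild-type enzyme, and PDGFA the platelet-derived growth factor A chain, a ligand of the receptor PDGFRA. The mouse genotype is N::TVA with floxed alleles that include Cdkn2a and Atrx, where TVA is the avian receptor that lets RCAS viruses infect mouse cells. The normal brains are from TVA-negative mice. The labels do not say whether the IDH1 tumours also received PDGFA, and they give no batch, sex, litter or pairing. The total count was 6507923, 9132783 and 10019818 in IDH1_R132H tumours 1 to 3, 14277395, 7023188 and 9886301 in IDH1WT tumours 1 to 3, 10110977, 10520489 and 9996171 in PDGFA tumours 1 to 3, and 8374528, 8704033 and 11731050 in normal brains 1 to 3. Each sample carries a number of its own in the labels, which do not say that each is a separate animal. The p-values here measure the spread between these samples. Levels are CPM, library-size normalised counts after TMM scaling, given as mean ± SD with n = 3 per group and n = 9 for all tumours. Coordinates are gene spans on GRCm38.

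Genes named in the genotypes were examined first. Atrx (chromosome X, 105797615 to 105929403) stood at 329, 336 and 262 CPM in the normal brains. It stood at 256, 269 and 264 in the IDH1_R132H tumours, 258, 212 and 297 in the IDH1WT tumours and 299, 288 and 286 in the PDGFA tumours. The tumour to normal log2 fold change was -0.2 (SE 0.13) for Atrx, with edgeR adjusted p = 0.39. Cdkn2a (chromosome 4, 89274471 to 89294653) had a count of 1 in each normal brain and of 0 to 14 in the tumours, below the level needed for testing. These are counts over whole genes. Floxed exons were not counted separately here, and a section also holds cells without recombination, so the levels check little about deletion. Idh1 (chromosome 1, 65158616 to 65186500) stood at 22.5, 23.8 and 27 CPM in the normal brains. It stood at 53.7, 52.2 and 70.7 in the IDH1_R132H tumours, 47.6, 56.3 and 39.1 in the IDH1WT tumours and 22.2, 36.2 and 46.7 in the PDGFA tumours. Pdgfa (chromosome 5, 138976014 to 138997370) stood at 30.5, 28.9 and 28.1 CPM in the normal brains. It stood at 42.4, 49 and 53.5 in the IDH1_R132H tumours, 44.3, 78.7 and 58.9 in the IDH1WT tumours and 57.1, 40.4 and 96.7 in the PDGFA tumours. Idh1 rose in tumours by 0.92 on the log2 scale (SE 0.21, edgeR adjusted p = 0.031) and Pdgfa by 0.98 (SE 0.24, adjusted p = 0.04). Viral transcripts were not told apart from the mouse genes.

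The tumours varied more than the normal brains. Over the 2000 most variable genes the first principal component took 48.2% of the variance and the second 14.2%. The normal brains lay at 45, 42.3 and 45.8 on the first component and PDGFA tumour 1 at 45.5, among them. PDGFA tumour 2 lay at 2.81, IDH1WT tumour 1 at -2.27, and the other tumours between -20.2 and -42.5. IDH1_R132H tumour 3 had 53.7% of its count on ribosomal-RNA-like loci, with 35.6% on Gm42418 alone, against 6.67% to 21.5% in the other libraries. The biological coefficient of variation was 14% among normal brains and 29.6% among tumours. Normal brains 1 and 2 were much alike, with a chi-square per gene of 2.77 against 33.5 and 32.3 for the other pairs of normal brains. The value of 2.77 exceeds the 1 that sampling noise alone gives, which does not show that they came from separate animals. They were kept as separate samples, and every p-value against normal brain treats them as independent.

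**Figure D1:**
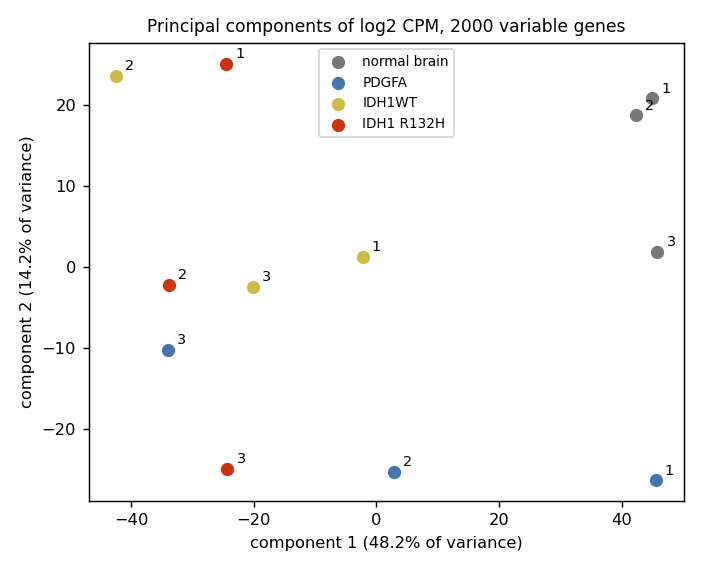
Each point is 1 library, placed by its first (48.2% of variance) and second (14.2%) principal component of log2 CPM over the 2000 most variable genes, coloured by group. PDGFA tumour 1 lies at 45.5 on the first component, beside the normal brains at 42.3 to 45.8.

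The first comparison asked what separates the 9 tumours, as the mean of the 3 tumour groups, from normal brain. Cell cycle genes and genes of oligodendrocyte precursors were among those that rose. Mki67, the proliferation antigen (chromosome 7, 135689784 to 135716361), stood at 1.92 ± 1.26 CPM in normal brain and 129 ± 92.6 in tumours, a log2 fold change of 6.03 (SE 0.8, edgeR adjusted p = 0.011). The DNA topoisomerase gene Top2a went from 1.86 ± 0.509 to 76.1 ± 44.8 CPM (log2 5.32, SE 0.74, adjusted p = 0.011). Pdgfra, the receptor that PDGFA binds (chromosome 5, 75152292 to 75198215), went from 48.6 ± 1.52 to 821 ± 548 CPM (log2 3.93, SE 0.68, adjusted p = 0.016). The lineage transcription factor Olig2 (chromosome 16, 91225457 to 91228677) went from 11 ± 1.65 to 117 ± 56.7 (log2 3.37, SE 0.52, adjusted p = 0.012). Pnlip, which encodes pancreatic lipase (chromosome 19, 58652498 to 58681788), had the largest rise by the naming rule, from 0.466 ± 0.135 to 42.4 ± 26.8 CPM, an 81.4-fold difference (log2 6.35, SE 0.91, adjusted p = 0.011). The others of the 10 named risers were the Notch ligand Dll3 (log2 5.25), the homeobox gene Meox1 (4.8), the mitotic genes Prc1 (4.74), Cenpf (4.73), Aspm (4.37) and Knl1 (4.35), and the oligodendrocyte lineage factor Zfp488 (4.13). Of the named genes that fell, the NMDA receptor subunit Grin2c fell by 1.38 (SE 0.27, adjusted p = 0.019), from 95 ± 6.58 to 36.8 ± 14 CPM. The corticotropin-releasing hormone receptor Crhr1, the potassium channel Kcnh3 and the cadherin Celsr3 changed by -1.25, -1.13 and -1.12. Exph5 (-1.43), Igfn1 (-1.25), Sowahb (-1.23), Svep1 (-1.21), Trmt9b (-1.14) and Plch2 (-1.07) complete the 10 named genes that fell. Of the other genes always reported, the astrocyte filament Gfap rose by 2.2 (SE 0.59, adjusted p = 0.049); Cd44 (2.08, adjusted p = 0.059), Trp53 (0.8, 0.12), Nf1 (0.18, 0.44) and Egfr (-0.18, 0.76) did not pass. In all, edgeR called 929 of 17812 genes, 661 higher and 268 lower, 615 of them by at least 2-fold. That count rests on few normal brains: without normal brain 1, 2 or 3 it was 0, 1 or 3, the last including the gene models A830036E02Rik and Nlrp5-ps. Without IDH1_R132H tumour 2 it was 367, without IDH1WT tumour 3 it was 598, and without PDGFA tumour 1 it was 2536. DESeq2 called 1993 genes (1414 higher) and limma voom with sample quality weights 6005 (2989 higher). The weights were 3.38, 3.06 and 0.783 for normal brains 1 to 3. They were 1.24, 3.19 and 0.475 for IDH1_R132H tumours 1 to 3 and 0.327 to 1.32 in the other tumours. The weighted fit thus leans most on normal brains 1 and 2, which were much alike, and on IDH1_R132H tumour 2. The count was 2204 for edgeR with no low count filter and 2928 without IDH1_R132H tumour 3 and PDGFA tumour 1 together.

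**Figure D2:**
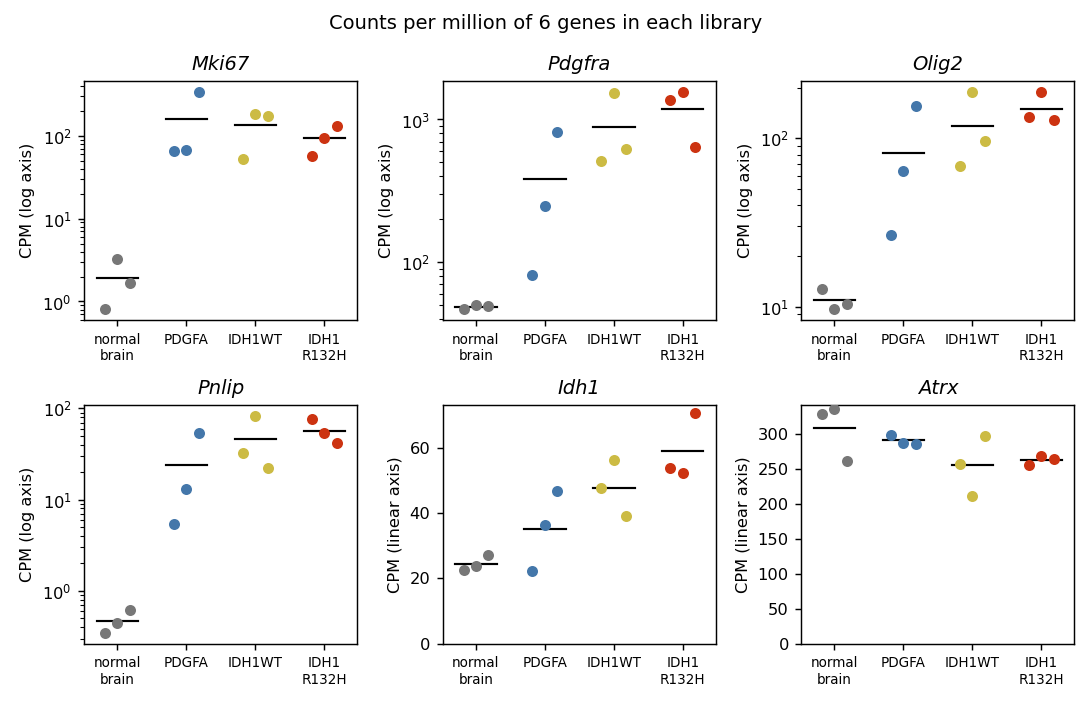
CPM of Mki67, Pdgfra, Olig2 and Pnlip (log axis) and of Idh1 and Atrx (linear axis) in each library, where points are libraries and lines group means (n = 3 per group). Pnlip stands at 0.466 ± 0.135 CPM in normal brain and 42.4 ± 26.8 in tumours, while Atrx stands at 309 ± 41.1 and 270 ± 27.2.

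Gene lists fixed before the data were examined were tested on the same comparison, beginning with the 4 glioma subtype lists. In the proneural list 13 of 28 members rose and 1 (Stmn1, a microtubule regulator, -0.73) fell, with a mean log2 change of 1.35. The risers include Olig2, the lineage factor Sox10 (2.91, SE 0.47, edgeR adjusted p = 0.015) and Marcksl1 (2.06). Of the classical list 5 of 29 rose (mean 0.38), among them the progenitor filament Nes (2.47, SE 0.47, edgeR adjusted p = 0.018), Sema6a (1.26) and Jag1 (1.18). Of the mesenchymal list 2 of 34 rose (mean 0.66), among them the TNF receptor Tnfrsf1a (2.34, SE 0.46, edgeR adjusted p = 0.02). No member of the neural list (16 genes, mean -0.45) passed. With p adjusted over the list alone, 17 higher and 1 lower passed in the proneural, 7 higher and 1 lower in the classical, 7 higher in the mesenchymal and 0 in the neural list. The lists were set against all other genes with camera, limma's competitive set test. Its adjusted p was 1.7e-10, 0.016, 0.00047 and 0.00052 in that order, and adjusted p = 0.17, 0.56, 0.52 and 0.52 with an estimated correlation.

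Among lists of cell types, markers of oligodendrocyte precursors moved furthest: 13 of 15 rose, with a mean log2 change of 2.84 (7.18-fold; camera adjusted p = 5.9e-20, adjusted p = 0.17 with an estimated correlation). Cspg4, the NG2 proteoglycan, rose by 3.88 (SE 0.63, edgeR adjusted p = 0.015). Endothelial markers rose in 6 of 15 (mean 0.61, camera adjusted p = 1.9e-06, adjusted p = 0.21 with an estimated correlation), among them the von Willebrand factor gene Vwf (1.62, SE 0.24, edgeR adjusted p = 0.012) and the VEGF receptor Kdr (1.22, SE 0.2, adjusted p = 0.015). Pericyte markers rose in 2 of 11, Rgs5 (0.77, SE 0.16, edgeR adjusted p = 0.021) and Abcc9 (1.51); the mean was 0.49 and the camera adjusted p 0.0073, with adjusted p = 0.38 with an estimated correlation. Microglia and macrophage markers averaged 1.04 (camera adjusted p = 9.9e-05, adjusted p = 0.52 with an estimated correlation) with 0 of 20 called. Their score was -2.21 in PDGFA tumour 1, below the normal brains (-0.97, -0.78 and -0.17), and -0.01 to 0.92 in the other tumours. The lysozyme gene Lyz2 (2.42) and Cd68 (1.68) had edgeR adjusted p = 0.061 and 0.065. Neuron markers averaged -0.39 (camera adjusted p = 0.00059, adjusted p = 0.54 with an estimated correlation) with 0 of 20 called, as for Rbfox3 (-0.77, edgeR adjusted p = 0.11). The camera test did not call astrocyte markers (mean -0.05, adjusted p = 0.29), myelinating oligodendrocyte markers (0.1, 0.72), T cell markers (0.3, 0.72), choroid plexus markers (-0.54, 0.071), red blood cell genes (0.16, 0.79) or fibroblast markers (0.69, 0.07). Of these lists, 1 astrocyte marker (Gfap), 1 myelinating marker (Ugt8a, 0.92, edgeR adjusted p = 0.042) and 1 fibroblast marker (Pdgfra) rose. Red blood cell genes had a median of -0.05 beside their mean of 0.16. When adjusted over the list alone, the risers numbered 15 for precursors, 9 for endothelium (1 lower), 4 for pericytes, 3 for microglia and 0 for neurons, T cells, choroid plexus and red blood cells, and 1 each for astrocytes, myelinating cells and fibroblasts.

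Among pathway lists, 17 of 20 mitosis genes rose, with a mean log2 change of 3.83 (14.3-fold; camera adjusted p = 2.3e-30), and 12 of 20 DNA replication genes rose (mean 1.78, 3.44-fold; 3.7e-15). Examples are the mitotic kinase Cdk1 (5.27), the hemimethylated DNA binder Uhrf1 (4.21, SE 0.6, edgeR adjusted p = 0.011) and the helicase subunit Mcm6 (3.51, SE 0.56, adjusted p = 0.015). With an estimated correlation the mitosis and replication lists had adjusted p = 0.17 and 0.18. Antigen presentation genes rose in 5 of 15 (mean 1.18; camera adjusted p = 3e-11, adjusted p = 0.17 with an estimated correlation), including the class I genes H2-K1 (1.58, SE 0.22, edgeR adjusted p = 0.011) and H2-D1 (1.41), close paralogs whose reads the counting could split, and the immunoproteasome subunit Psmb8 (2.18, SE 0.32, edgeR adjusted p = 0.012). Interferon response genes rose in 4 of 18 (mean 1.11; camera adjusted p = 2.8e-08, adjusted p = 0.21 with an estimated correlation), such as the RNA sensor Ddx58 (1.71) and Ifit2 (1.34). Collagens and matrix genes rose in 7 of 20 (mean 0.93; camera adjusted p = 5.4e-09, adjusted p = 0.21 with an estimated correlation), among them the basement membrane genes Col4a1 (1.96), Nid1 (1.9) and Lamc1 (1.35). Receptor tyrosine kinase and MAPK feedback genes rose in 7 of 17 (mean 1.07; camera adjusted p = 6e-07, adjusted p = 0.17 with an estimated correlation), such as Ccnd1 (3.35), Spry1 (2.34), Spry4 (2.22) and Dusp6 (0.93). Of the p53 targets 2 of 18 rose, Cdkn1a (2.63, SE 0.57, edgeR adjusted p = 0.027) and Eda2r (4.21, SE 1, adjusted p = 0.035); the list mean was 0.83, with camera adjusted p = 0.00012 and adjusted p = 0.29 with an estimated correlation.

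The metabolic lists moved less. In the isocitrate dehydrogenase and TCA cycle list 2 of 20 rose, Idh1 and the cytosolic aconitase Aco1 (0.62, edgeR adjusted p = 0.028), around a mean of -0.02 (camera adjusted p = 0.82). Among 2-oxoglutarate dependent dioxygenases 3 of 20 rose, including the lysyl hydroxylase Plod1 (1.12) and the methylcytosine dioxygenase Tet1 (0.72), and the prolyl hydroxylase subunit P4ha2 changed by -0.77; the mean was 0.28 (camera adjusted p = 0.02, adjusted p = 0.44 with an estimated correlation). In the glutamate and branched-chain amino acid list Aldh18a1 (0.77) and Gpt2 (1.28) rose and the glutaminase Gls2 (-0.85) fell, around a mean of 0.03 and a median of -0.08 (camera adjusted p = 0.98). Hypoxia and glycolysis genes averaged 0.4 (camera adjusted p = 0.057), with the peptide hormone gene Adm (3.31) and Egln3 (0.97) higher. Genes known as lower in human IDH-mutant glioma averaged 0.43 (camera adjusted p = 0.067; 0 of 12 called), and lipid and cholesterol synthesis genes 0.23 (0.0059, adjusted p = 0.38 with an estimated correlation), with Sqle (0.6) the 1 member that rose. The risers adjusted over the list alone were 20 mitosis, 16 replication, 11 antigen presentation, 11 interferon, 9 matrix, 9 MAPK feedback, 6 p53, 5 lipid, 3 hypoxia, 2 TCA, 2 glutamate (1 lower) and 5 dioxygenase genes (2 lower), and 0 of the genes lower in human IDH-mutant glioma. Across the 28 lists camera with its preset correlation of 0.01 called 16 higher and 2 lower, and 0 were called with an estimated correlation (smallest adjusted p = 0.17). Limma's rotation test fry, which asks whether a list's genes move on balance one way, called 11, all higher. The 11 are the proneural, precursor, endothelial, replication, mitosis, interferon, antigen presentation, matrix, p53, MAPK feedback and lipid lists. Lists share members; Pdgfra, Olig2, Sox10 and Gpr17 are in both the proneural and the precursor list. Leaving out IDH1_R132H tumour 3 and PDGFA tumour 1 together ended the camera calls of the pericyte list (adjusted p = 0.085) and the lipid list (0.061), and leaving out normal brain 3 that of the dioxygenase list (0.079).

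**Figure D3:**
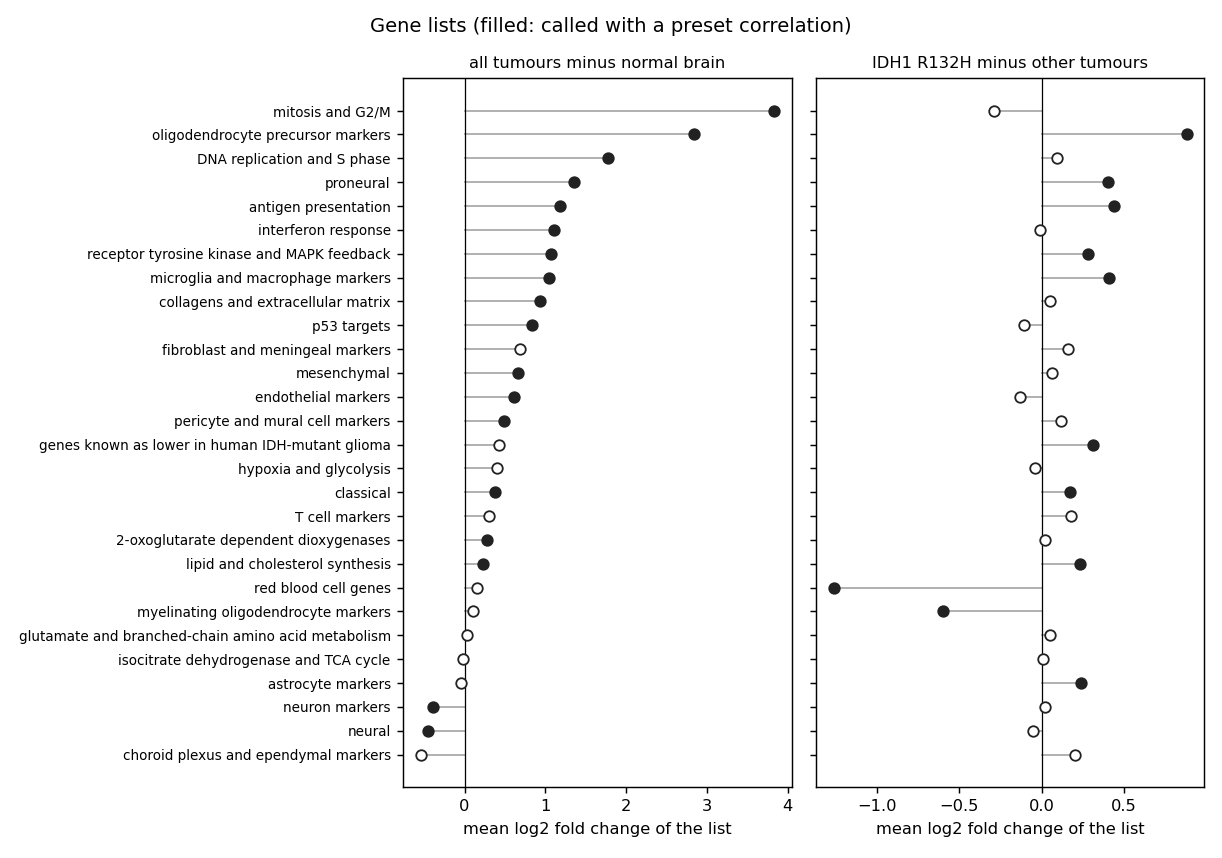
Mean log2 fold change of the tested members of each of the 28 gene lists in tumours against normal brain and in IDH1_R132H against the other tumours; filled points were called by camera with its preset correlation. Mitosis genes stand at 3.83 and oligodendrocyte precursor markers at 2.84 in tumours against normal brain, and at an estimated correlation 0 lists were called in either comparison.

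The series names determination of the glioma subtype as its aim, and each library was scored on the 4 subtype lists as the mean log2 CPM of the members relative to the 12 libraries. The proneural score averaged 0.63 ± 0.21 in the IDH1_R132H tumours (n = 3) and 0.14 ± 0.5 in the other tumours (n = 6), a difference of 0.49 with p = 0.15 by an exact two-sided permutation test over 84 splits (adjusted over the 4 scores, 0.6). The classical score differed by 0.29 (0.26 ± 0.07 against -0.03 ± 0.55, exact p = 0.48), the mesenchymal by 0.14 (0.23 ± 0.33 against 0.09 ± 0.58, exact p = 0.8) and the neural by -0.03 (-0.15 ± 0.47 against -0.12 ± 0.45, exact p = 0.95), each with an adjusted p of 0.95. Group means of the proneural score were 0.34 in IDH1WT tumours, -0.06 in PDGFA tumours and -0.91 in normal brain. The score that stood highest was proneural in 4 tumours (IDH1_R132H 1 and 2, IDH1WT 2 and PDGFA 3). It was mesenchymal in 3 (IDH1_R132H 3, IDH1WT 3 and PDGFA 2), neural in 2 (IDH1WT 1 and PDGFA 1) and classical in 0. In the 3 normal brains it was neural. Some margins were small, with mesenchymal 0.51 against proneural 0.44 in IDH1_R132H tumour 3. In PDGFA tumour 3 proneural stood at 0.52 against mesenchymal 0.41. Each score is relative to its own list's mean over the 12 libraries, so the highest one does not assign a subtype. No subtype score separated the IDH1_R132H from the other tumours in this test, and a comparison of 3 against 3 libraries cannot go below p = 0.1 in this exact test. Without PDGFA tumour 1 the proneural, classical, mesenchymal and neural differences were 0.32, 0.07, -0.09 and 0.07. The mesenchymal difference was 0.32 without IDH1_R132H tumour 1, 0 without IDH1_R132H tumour 3 and 0.23 without IDH1WT tumour 3. The neural difference was 0.13, 0.07 and -0.3 without IDH1_R132H tumours 1 to 3, 0.01 and -0.13 without PDGFA tumours 2 and 3, and 0.05, -0.13 and -0.07 without IDH1WT tumours 1 to 3.

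**Figure D4:**
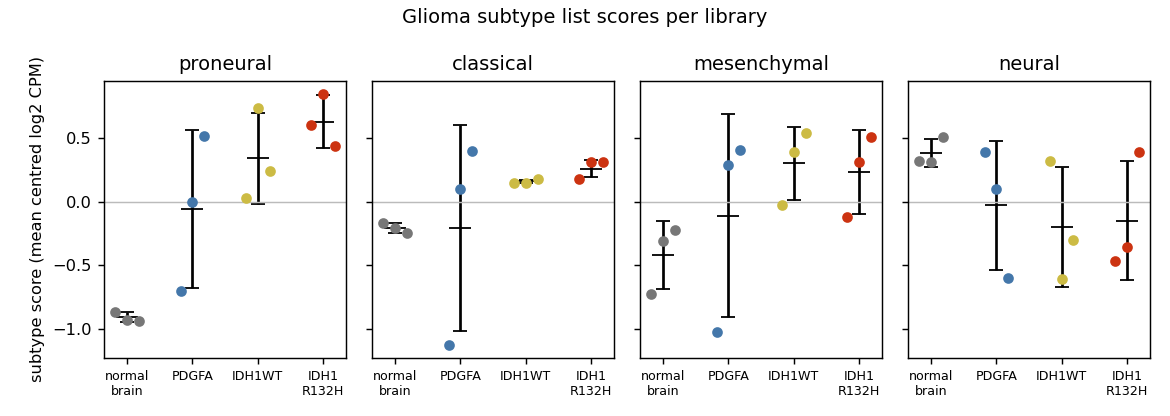
Subtype score of each library (points; log2 units relative to the mean of the 12 libraries) for the 4 lists, with the mean ± SD of each group of 3. The proneural score of the IDH1_R132H tumours is 0.63 ± 0.21 and that of normal brain averages -0.91.

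The second comparison set the 3 IDH1_R132H tumours against the mean of the IDH1WT and PDGFA tumours, the contrast of mutant with wild-type tumours named in the series design. Markers of oligodendrocyte precursors stood higher in the mutant tumours by a mean log2 of 0.88 (1.84-fold) and markers of myelinating oligodendrocytes lower by a mean of -0.6, the latter beside high levels in PDGFA tumour 1. There the myelin gene Mobp stood at 1700 CPM against 401 ± 2.83 in normal brain. The precursor score was -1.63 in PDGFA tumour 1 and -0.39 to 1.89 in the other tumours. In IDH1_R132H tumour 3 it was 0.5, below IDH1WT tumours 2 and 3 (1.79, 0.84) and PDGFA tumour 3 (1.07). The precursor difference was 0.68 without PDGFA tumour 1 and 1.36 without PDGFA tumour 3, called by camera's preset test in both. With all libraries and an estimated correlation its adjusted p was 0.5, not called. Among precursor markers, the differences were 1.1 for Cacng4, 1.06 for Tnr (SE 0.36) and 1.58 for Neu4; among myelin genes, -1.13 for Mobp (SE 0.34) and -0.93 for Mal, with edgeR adjusted p = 0.69 for Tnr and Mobp. Idh1 differed by 0.52 (SE 0.21, edgeR adjusted p = 0.74), Pdgfra by 1.03 (SE 0.54, adjusted p = 0.78), Olig2 by 0.61 (adjusted p = 0.83), Pdgfa by -0.37 (0.82) and Mki67 by -0.63 (0.87). The smallest adjusted p was that of Gfra2, the neurturin receptor, at 61.2 ± 6.38 CPM in IDH1_R132H, 37.7 ± 3.59 in IDH1WT and 30 ± 4.28 in PDGFA tumours (log2 0.87, SE 0.13, edgeR adjusted p = 0.23). In this comparison edgeR called 0 genes, with 1147 at an unadjusted p under 0.05 where chance gives 891. DESeq2 called 25 (20 higher), limma voom with sample quality weights 245 (165 higher) and limma on the deposited log2 values 0. With no low count filter edgeR called 278, and without IDH1WT tumour 2 or 3 it called 1 gene each, Stk32b and Fndc9. With the level of neuron markers as a covariate edgeR called 33 (31 higher) on the 9 tumours in 3 groups. With that covariate it called 0 on the 9 tumours in 2 groups and 33 over 12 libraries, 18 of them shared. Chosen after their values were seen, the DESeq2 genes include Gfra2 (DESeq2 adjusted p = 3.1e-05), the otoferlin gene Otof (-1.65, 0.00062) and Stk32b (1.53, 0.0011). They also include the neuropeptide gene Npy (2.07, 0.0051), Meox1 (1.91, 0.017) and the hypoxia-inducible factor Epas1 (0.82, 0.019). The edgeR adjusted p of these genes was 0.23 to 0.49. In the simulation of this comparison, with 200 genes changed, DESeq2 made 31 false calls and edgeR 8. Which of the DESeq2 genes differ is therefore not settled.

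With its preset correlation camera called 11 of the 28 lists in this comparison, and 0 with an estimated correlation or by fry. The 9 higher lists were oligodendrocyte precursor markers (camera adjusted p = 7.5e-10), proneural (mean 0.4, 4.2e-06), antigen presentation (0.44, 8.8e-05; H2-Ab1 1.1), lipid and cholesterol synthesis (0.23, 0.00019), microglia and macrophages (0.41, 0.00035), MAPK feedback (0.28, 0.00076; Spred2 0.54), classical (0.17, 0.0073), astrocytes (0.24, 0.0074; Atp1b2 0.92) and genes known as lower in human IDH-mutant glioma (0.31, 0.03). The 2 lower lists were myelinating oligodendrocytes (3.3e-07) and red blood cell genes (-1.26, 0.019; Alas2 -1.79). With an estimated correlation these lists had adjusted p = 0.5 (precursor, proneural, myelinating, MAPK feedback and lipid), adjusted p = 0.63 (antigen presentation) or adjusted p = 0.81 (the other lists called). Adjusted over the list alone, 1 gene passed, the T cell costimulatory receptor Cd28 (1.77, SE 0.45; edgeR adjusted p over all genes 0.63). PDGFA tumour 1 held low levels of astrocyte and microglia genes, and without it the astrocyte (mean 0.05), microglia (0.17), classical (0.03), red blood cell (-1.35) and human IDH-mutant (0.14) lists were no longer called. Other libraries also decided list calls: without IDH1_R132H tumour 3 the astrocyte (0.07), classical (0.14), lipid (0.1) and human IDH-mutant (0.17) lists were lost and neuron markers averaged -0.37. Antigen presentation was lost without IDH1_R132H tumour 1 (0.22, adjusted p = 0.059), and the human IDH-mutant (0.25) and red blood cell lists (-0.87) without IDH1_R132H tumour 2. The astrocyte (0.15) and human IDH-mutant lists (0.33) were lost without IDH1WT tumour 2, and the red blood cell list without IDH1WT tumour 3 (-0.88) or PDGFA tumour 2 (-0.62). The precursor, proneural, myelinating and MAPK feedback lists kept the same direction and stayed called by camera's preset test in each of the 9 fits that left out 1 tumour.

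The IDH1_R132H and IDH1WT tumours, which differ in the labels only by the form of IDH1, were compared next. With 3 libraries in each group edgeR recovered 34.3% of 2-fold changes in simulation, so few calls do not show that the groups are alike. Idh1 differed by 0.3 (SE 0.24, edgeR adjusted p = 1) and Mki67 by -0.53 (SE 0.64, adjusted p = 1). Precursor markers stood higher by a mean of 0.39 and microglia markers by 0.39; pericyte markers stood lower by a mean of -0.3 and endothelial markers by -0.23. Lipid and cholesterol synthesis genes stood higher by a mean of 0.22, with 0.5 for Srebf2 (SE 0.2), a transcription factor of sterol synthesis genes (edgeR adjusted p = 1). edgeR called 0 genes, with 475 at an unadjusted p under 0.05 where chance gives 891. DESeq2 called 0, limma voom with sample quality weights 0, and edgeR with no low count filter 79. With its preset correlation camera called the lists just named, proneural (0.25), antigen presentation (0.2) and MAPK feedback (0.25) higher and myelinating oligodendrocytes (-0.23) lower, 9 in all, with the smallest adjusted p 0.00095 for lipid synthesis and adjusted p = 0.95 with an estimated correlation for each. Each of the 9 calls was lost without some single library. The precursor call was lost without IDH1_R132H tumour 1 (mean 0.32) or 2 (0.13) or IDH1WT tumour 1 (0.11) or 3 (0.31). The myelin call was lost without the same libraries (-0.19, -0.23, -0.07 and -0.12), as was that of antigen presentation (-0.02, 0.2, 0 and 0.16). Without IDH1_R132H tumour 1 or IDH1WT tumour 3 the pericyte (-0.11 and -0.11) and endothelial calls (-0.15 and -0.11) were lost. The microglia call was lost without IDH1_R132H tumour 2 (0.23) or 3 (0.29) or IDH1WT tumour 2 (0.28). The proneural call was lost without IDH1_R132H tumour 2 (0.14) or IDH1WT tumour 1 (0.13), and the lipid call without IDH1_R132H tumour 3 (0.1) or IDH1WT tumour 2 (0.18). The MAPK feedback call was lost without IDH1WT tumour 1 (0.15) or 3 (0.18). Adjusted over the list alone, 0 members passed; the lists called numbered 3 without IDH1WT tumour 3, 5 without IDH1_R132H tumour 2 and 14 without IDH1_R132H tumour 3 and PDGFA tumour 1 together.

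Against the PDGFA tumours, the IDH1_R132H tumours held more of the precursor markers (mean 1.37, 2.59-fold; Neu4 2.64, SE 0.77) and less of the myelin markers (mean -0.98; Mobp -1.75, SE 0.39). Without PDGFA tumour 3 the precursor mean was 2.31, and without PDGFA tumour 1 the myelin mean was -0.59. Red blood cell genes differed by a mean of -2.13, but their score was 1.33, 2.78 and -2.1 in the PDGFA tumours, the last below every IDH1_R132H tumour (-0.44, -1.58 and 0.16). Their camera call was lost without PDGFA tumour 2 (-0.85) or IDH1_R132H tumour 2 (-1.75). Antigen presentation genes stood higher by a mean of 0.68, with 1.72 for the class II gene H2-Aa (SE 0.4, edgeR adjusted p = 0.27), and astrocyte markers by 0.45, with 0.98 for S100b (SE 0.23, adjusted p = 0.27). The astrocyte difference rests on PDGFA tumour 1, with a score of -2.14 against 0.38 and 0.01 in PDGFA tumours 2 and 3 and -0.1, 0.3 and 0.52 in IDH1_R132H. Without that tumour it was 0.06 and not called; it was 0.88 without PDGFA tumour 2 and 0.27 without IDH1_R132H tumour 3. Adjusted over the list alone, 3 precursor, 4 antigen presentation, 2 astrocyte, 1 proneural, 1 pericyte and 1 T cell gene passed as higher and 6 myelin and 5 red blood cell genes as lower. Idh1 differed by 0.74 (SE 0.24, edgeR adjusted p = 0.36) and Pdgfra by 1.64 (SE 0.66, adjusted p = 0.41). With its preset correlation camera called 14 lists higher and 2 lower, led by precursors (8.5e-12) and myelin (2.8e-10), with adjusted p = 0.47 to 0.72 with an estimated correlation. Of these 16 calls 7 remained without PDGFA tumour 1, which also lost classical (mean -0.03), mesenchymal (-0.06), microglia (-0.05), fibroblast (0.03), replication (-0.09), matrix (0.02), MAPK feedback (0.18) and human IDH-mutant genes (0.04). Without IDH1_R132H tumour 3, 9 remained, with mesenchymal (0.02), fibroblast (0.28), replication (0.09), matrix (0.11), MAPK feedback (0.22), human IDH-mutant (0.24) and lipid genes (0.1) lost. Without IDH1_R132H tumour 2, 10 remained, with mesenchymal (0.2), fibroblast (0.37), replication (0.2), matrix (0.24) and human IDH-mutant genes (0.32) lost beside red blood cells. Without PDGFA tumour 2, replication (-0.04) and lipid genes (0.17) were lost as well. edgeR called 0 genes, with 1940 at an unadjusted p under 0.05, DESeq2 128 (60 higher), limma voom with sample quality weights 396 (216 higher) and limma on the deposited log2 values 0. The count was 627 for edgeR with no low count filter and 67 (57 higher) with the neuron marker covariate, fitted without the normal brains. Without PDGFA tumour 3 edgeR called 43 genes, and without PDGFA tumour 1 it called 1, the ribosomal protein gene model Rps3a3.

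Between IDH1WT and PDGFA tumours, pericyte markers stood higher in IDH1WT by a mean of 0.83 (1.78-fold), and Rgs5, a pericyte signalling regulator, stood at 204 ± 51.9 CPM against 105 ± 11.6 (log2 0.96, SE 0.18, edgeR adjusted p = 0.62). Collagens and matrix genes stood higher by a mean of 0.46, precursor markers by 0.98, and myelin markers lower by -0.75 (Mobp -1.25, SE 0.38). Without PDGFA tumour 1 the means were 0.19 for matrix, no longer called, 0.54 for precursors and -0.35 for myelin. The precursor mean was 1.9 without PDGFA tumour 3 and 0.44 without IDH1WT tumour 2, and the matrix mean 0.3 without IDH1WT tumour 3. Red blood cell genes differed by a mean of -1.74, a call lost without PDGFA tumour 1 (-1.9) or 2 (-0.46) or IDH1WT tumour 1 (-1.48). Adjusted over the list alone, 5 of 11 pericyte genes and 6 matrix genes passed as higher, 1 matrix gene and 4 myelin genes as lower, and 2 antigen presentation, 1 astrocyte and 1 T cell gene as higher. With its preset correlation camera called 12 lists higher and 3 lower; pericyte markers had the smallest p (4.9e-12), with adjusted p = 0.1 with an estimated correlation and a fry adjusted p of 0.061, and the other lists called had adjusted p = 0.68 or 0.74 with an estimated correlation. edgeR called 0 genes, with 1038 at an unadjusted p under 0.05, DESeq2 10 (7 higher), limma voom with sample quality weights 0, limma on the deposited log2 values 0 and edgeR with no low count filter 261. Without PDGFA tumour 1 camera called 8 lists, only 4 of them among the 15. It lost proneural (mean 0.07), classical (-0.12), mesenchymal (-0.02), neuron (0.05), astrocyte (0.01), fibroblast (0.13), replication (-0.09), mitosis (-0.28) and antigen presentation genes (0.3) beside matrix and red blood cells. Without IDH1WT tumour 2, proneural (0.02), neuron (-0.1), replication (0.11), mitosis (-0.18) and antigen presentation genes (0.15) were lost. Without IDH1WT tumour 3, mesenchymal (0.12), endothelial (0.07), replication (0.13) and mitosis genes (0.06) were lost. The endothelial call was also lost without PDGFA tumour 2 (0.04) or 3 (0.25) or IDH1WT tumour 1 (0.24), and those of replication (-0.03) and mitosis (-0.12) without PDGFA tumour 2. Without PDGFA tumour 1 edgeR called 1 gene (Rps3a3), and without that tumour and IDH1_R132H tumour 3 edgeR called Rps3a3, Rps3a1 and Gpatch4.

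Each tumour group was also set against normal brain. In the IDH1_R132H tumours Pnlip rose by 6.86 (SE 0.96), Meox1 by 6.07 (SE 0.67) and Mki67 by 5.61 (SE 0.83). Otof, needed for synaptic vesicle release in inner hair cells, fell by 2.31 (SE 0.32). The ephrin receptor Epha8 fell by 2.04 and Exph5 fell by 2.02. Idh1 rose by 1.26 (SE 0.25, edgeR adjusted p = 0.019), Pdgfra by 4.61 (SE 0.75, adjusted p = 0.014) and Gfap by 2.49 (SE 0.66, adjusted p = 0.041). All 15 precursor markers rose (mean 3.43), as did 17 of 20 mitosis (3.64), 11 replication (1.84), 9 antigen presentation (1.48) and 6 matrix genes (0.96); 0 neuron markers were called (mean -0.38; -0.2 without IDH1_R132H tumour 1 and -0.77 without tumour 3). In the IDH1WT tumours Pnlip (6.55), Mki67 (6.13) and Top2a (5.57) rose, Fcho1 (-1.25), the antisense transcript Dlx6os1 (-1.1) and Celf3 (-1.09) fell. Pdgfra rose by 4.2 (SE 0.74, edgeR adjusted p = 0.024). In that group 16 mitosis (mean 4.02), 8 precursor (3.04), 5 replication, 5 antigen presentation and 5 matrix genes rose. Idh1 (0.96, edgeR adjusted p = 0.064), Pdgfa (1.05, 0.075) and Gfap (1.96, 0.13) did not pass in that group. In the PDGFA tumours Mki67 (6.34), Pnlip (5.63) and Top2a (5.24) rose, the alarmin Il33 (-2.02), Igfn1 (-1.55) and Cdyl (-1.14) fell. Pdgfra (2.97, edgeR adjusted p = 0.1), Pdgfa (1.15, 0.12) and Idh1 (0.52, 0.48) did not pass. There 5 mitosis, 3 replication and 3 antigen presentation genes rose and 0 of 15 precursor markers (mean 2.06) were called, while 12 precursor markers passed adjusted over the list alone; myelin markers averaged 0.68 and astrocyte markers -0.34. Both rest on PDGFA tumour 1: without it they averaged 0.28 and 0.05 and camera called neither. Without PDGFA tumour 2 the astrocyte mean was -0.77, and without PDGFA tumour 3 the precursor mean was 1.12.

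edgeR called 1278 genes for IDH1_R132H (860 higher, 418 lower), 307 for IDH1WT (280 and 27) and 54 for PDGFA (46 and 8) against normal brain. These counts do not rank the groups, because the difference between groups is tested only in the comparisons among tumours. Camera with its preset correlation called 18 lists in each, and 0 with an estimated correlation (smallest adjusted p = 0.17, 0.13 and 0.18). Of the 18, at least 15, 17 and 14 remained called without any 1 library. Every count depended on single libraries, and the single genes called without normal brain 3 were A830036E02Rik each time. For IDH1_R132H it was 0, 0 and 1 without normal brains 1 to 3, and 635, 1 (Meox1) and 854 without tumours 1 to 3. For IDH1WT it was 1 (Apold1), 0 and 1 without normal brains 1 to 3, and 687, 0 and 0 without tumours 1 to 3. For PDGFA it was 0, 0 and 1 without normal brains 1 to 3, and 828, 18 and 19 without tumours 1 to 3. DESeq2 called 2342, 1225 and 471, and limma voom with sample quality weights 7320, 3008 and 436. edgeR called 2468, 1555 and 958 with no low count filter and 3319, 1426 and 0 on the 6 libraries compared alone. edgeR called 2167, 1300 and 970 without IDH1_R132H tumour 3 and PDGFA tumour 1 together. Limma on the deposited log2 values called 1208, 113 and 0.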

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

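No test in this part was chosen after the result was seen; the values without 1 library were. The 28 lists and 286 named genes were searched for cases in which every library of 1 tumour group lay above the mean of normal brain and every library of another lay below it, and 5 genes were found. The differences were not tested by that search, so the edgeR adjusted p of the difference between the tumour groups is given beside each. The naming rule takes the members of each list with the smallest p in the comparisons between tumour groups. S100b, Mobp, Mal and Cd28 were named that way for IDH1WT against PDGFA. The search therefore reuses differences already picked from these libraries. How many cases chance would give was not estimated.

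Relative to normal brain, the myelin gene Mobp stood 1.18 higher in the PDGFA tumours and at -0.43 in the IDH1_R132H tumours, a gap of 1.61 on the log2 scale (edgeR adjusted p = 0.25), and the myelin gene Mal stood at 0.9 and -0.49, a gap of 1.39 (adjusted p = 0.28). For Mobp the PDGFA value was 0.73 without PDGFA tumour 1, and the IDH1_R132H value was -0.26 without IDH1_R132H tumour 1. The T cell costimulatory receptor gene Cd28 stood at 1.38 in the IDH1_R132H and -0.81 in the PDGFA tumours, a gap of 2.18 (edgeR adjusted p = 0.24); without PDGFA tumour 2 the latter was -0.53. The MAPK feedback gene Spred2 stood at 0.45 and -0.14 in the same groups, a gap of 0.59 (edgeR adjusted p = 0.33). Without IDH1_R132H tumour 3 the former was 0.25 and the gap 0.39, and the latter was -0.21 without PDGFA tumour 2 and -0.09 without PDGFA tumour 3. The astrocyte gene S100b stood at 0.21 in the IDH1WT and -0.78 in the PDGFA tumours, a gap of 0.99 (edgeR adjusted p = 0.81). The IDH1WT value was 0.05 without IDH1WT tumour 2, and 0.12, 0.12 and 0.41 without normal brains 1 to 3.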

How the results depend on the processing

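Leaving out IDH1_R132H tumour 3 and PDGFA tumour 1 together, leaving out ribosomal-RNA-like loci and the sex covariate were chosen after the data were seen; the other alternatives were planned. No paired analysis was possible because the labels give no replicate numbers that groups share. The cause of the differences below was not tested, except that leaving out libraries leaves fewer samples and the fold change minimum removes genes by construction. Counts of genes are given in the order tumours against normal brain, IDH1_R132H against other tumours, against IDH1WT and against PDGFA, IDH1WT against PDGFA, then IDH1_R132H, IDH1WT and PDGFA against normal brain; edgeR gave 929, 0, 0, 0, 0, 1278, 307 and 54. DESeq2 gave 1993 (922 shared with edgeR), 25, 0, 128, 10, 2342, 1225 and 471. Limma voom with sample quality weights gave 6005, 245, 0, 396, 0, 7320, 3008 and 436. No low count filter gave 2204, 278, 79, 627, 261, 2468, 1555 and 958. Limma on the deposited log2 values gave 862, 0, 0, 0, 0, 1208, 113 and 0. The stricter filter gave 24 for PDGFA against normal brain, and the fold change minimum 615 for tumours against normal brain. Fitting only the groups compared gave 3319, 1426 and 0 against normal brain. The neuron marker covariate, fitted on the 9 tumours without the normal brains, gave 33 for IDH1_R132H against other tumours, 67 against PDGFA and 0 against IDH1WT. Leaving out the 2 libraries gave 2928, 0, 0, 1, 3, 2167, 1300 and 970. The sex covariate gave 798 for IDH1_R132H and 0 for PDGFA against normal brain. RLE factors and leaving out ribosomal-RNA-like loci kept each count within 1.5 times.

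Leaving out 1 library at a time gave 0 to 2536 genes for tumours against normal brain, 0 to 1 for IDH1_R132H against other tumours, 0 to 0 against IDH1WT, 0 to 43 against PDGFA, 0 to 1 for IDH1WT against PDGFA, and 0 to 854, 0 to 687 and 0 to 828 for IDH1_R132H, IDH1WT and PDGFA against normal brain. Called lists ranged from 18 to 22, 9 to 14, 3 to 12, 11 to 19, 8 to 17, 15 to 19, 17 to 20 and 15 to 19 in the same order. Subtype differences ranged from 0.32 to 0.61 (proneural), 0.07 to 0.37 (classical), -0.09 to 0.32 (mesenchymal) and -0.3 to 0.13 (neural), and no exact p fell below 0.089.

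An estimated correlation left 0 called lists in each of the 8 comparisons. The rotation test left 11, 10 and 10 for all tumours, IDH1_R132H and IDH1WT against normal brain and 0 in the others. Without the 2 libraries, 14 lists were called for IDH1_R132H against IDH1WT and 8 for IDH1WT against PDGFA. In IDH1_R132H against other tumours 5 lists that camera called with all libraries or under the alternative changed the direction of their camera test. Neuron markers (0.02 with all libraries, -0.37 to 0.21 when 1 was left out) went to -0.37 without IDH1_R132H tumour 3. Without the 2 libraries mesenchymal went to -0.24, astrocyte to -0.12, and collagens and matrix to -0.24. There the list lower in human IDH-mutant glioma went to 0.01 with the test pointing down. For lists called in neither fit the direction was not compared. Named genes were followed under RLE factors, DESeq2, limma voom with sample quality weights, the neuron marker covariate and leaving out 1 library. Of those values 3791 stayed on their side of the threshold, 397 lost and 142 gained a call. The other alternatives were not followed for single genes. None that was called in either fit changed direction. For genes called in neither fit the direction was not compared.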

Other observations

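Tests chosen after the result was seen were the splits of the neuron covariate fit over 12 libraries, the splits of both neuron covariate fits at an unadjusted p under 0.05, the tests of PDGFA tumour 1 other than the GC and length correction, and all relations of Pnlip and Meox1, with the pancreatic genes. The GC and length correction was set before its own result was known, but after the low markers of that tumour had been seen.

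PDGFA tumour 1 held a set of brain genes apart from the other libraries. The activity-dependent genes Npas4 and Fosb stood at 222 and 161 CPM there, against 11.3 ± 4.02 and 8.3 ± 0.744 in normal brain (n = 3). The striatal neuron gene Drd1 stood at 66.7 CPM against 26.5 ± 7.29, and Mbp at 5920 against 1740 ± 57.7. The astrocyte genes Slc1a3 and Gpr37l1 stood at 31.2 and 9.06 CPM against 415 ± 15.8 and 118 ± 18.6, and the microglial genes Csf1r and Tmem119 at 5.7 and 0.671 against 37 ± 10.4 and 9.78 ± 2.91. Mitosis genes scored 1.59 above the highest normal brain on the log2 scale and precursor markers 0.27 above it.

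This tumour lies beside normal brain on the first principal component, and a section mostly of the same tissue as the normal brains would put its astrocyte and microglia markers between normal brain and the other tumours. They lay below the lowest other library, by -1.24 for microglia and -1.89 for astrocytes, which argues against that explanation. GC content and gene length bias is also argued against: the mean deviation of the 35 markers from normal brain was -1.84 after correction and -1.89 before, against -0.22 to 0.2 for random lists. Tissue from another brain region remains open. Striatal markers lay 1.1 above the highest normal brain, which goes with it. Cortical markers lay inside the range of the normal brains, which goes against it. They were only 0.04 above the lowest normal brain, less than the SD of 0.12 among the normal brains, so they do not decide. The biology of the tumour cells themselves was not tested and stays open.

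Pnlip rose in the tumours, and pancreatic tissue or RNA in the tumour samples could bring it. Over the 9 tumours 21 other pancreatic genes had a median count of 8 against 3504 for Pnlip, and 17 of them lay under 1% of it, which argues against that explanation. Their summed count of 633 (18.1%, with 369 from Cela1) lies between the levels set for and against it and alone decides nothing; the median was chosen, with its level, after these counts were seen. Pnlip may instead follow the amount of precursor-like cells: over the 9 tumours it correlated with the precursor marker score (Pearson r = 0.93, exact permutation p = 0.00056, adjusted over 4 relations 0.0022; Spearman rho = 0.85, exact p = 0.0061, adjusted 0.012), with r = 0.72 without PDGFA tumours 1 and 2. With the mitosis score r was 0.64 over the 9 tumours (exact p = 0.061, adjusted 0.081; rho 0.57, p = 0.12) and 0.28 without PDGFA tumours 1 and 3.

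Meox1 followed the precursor score with r = 0.88 (exact p = 0.0015, adjusted 0.003; rho 0.85, exact p = 0.0061) and 0.67 without PDGFA tumours 1 and 2. With the mitosis score r was 0.43 (exact p = 0.25, adjusted 0.25; rho 0.25, exact p = 0.52) and 0.26 without PDGFA tumours 1 and 3. The relations of both genes were found and tested on the same libraries and are hypotheses.

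Other splits of the libraries were refitted for each count of genes. For tumours against normal brain, refitted as 2 groups, the real split gave 782 genes. The 100 splits fitted were the real one and a random draw of the others. Counting the real split, 2 of 100 gave at least as many. The highest other gave 846, more than the real split, and exchanged PDGFA tumour 1 with normal brain 3. The share is under 0.05, but it concerns only the count of genes. With 1 coefficient per group, that count fell to few or no genes without any 1 normal brain. For IDH1_R132H against other tumours the real split gave 0 genes, so all 84 splits had to give as many, which says nothing about chance. The highest other gave 1714 with PDGFA tumours 1 and 2 and IDH1WT tumour 1 together. Among the tumours these lay nearest normal brain on the first principal component (45.5, 2.81 and -2.27). Their precursor scores (-1.63, -0.39 and 0.16) were also the lowest of the tumours. That split was picked for its size, and what sets these tumours apart was not tested. At an unadjusted p under 0.05 the real split gave 1046 genes and 31 of 84 splits gave as many (highest other 4957), so chance is not excluded.

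With 3 against 3 libraries there are 10 splits and the share cannot go under 0.05. The real and highest other counts were 0 and 0 for IDH1_R132H against IDH1WT (10 of 10 splits as large), 0 and 0 against PDGFA (10 of 10), and 0 and 1558 for IDH1WT against PDGFA (10 of 10), the last again with PDGFA tumours 1 and 2 and IDH1WT tumour 1 together. Against normal brain they were 1278 and 0 for IDH1_R132H, 307 and 0 for IDH1WT, and 54 and 0 for PDGFA, each with 1 of 10 splits as large.

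With the level of neuron markers as a covariate the 9 tumours in 3 groups gave 33 genes between IDH1_R132H and the other tumours, among them Tnr (1.14, edgeR adjusted p = 0.018), Meox1 (2.1, 0.022), Pdgfra (1.39, 0.039) and Npy (2.16, 0.039). Over 12 libraries the fit gave 33 genes, 18 of them shared. Npy was called there (edgeR adjusted p = 0.018), but Tnr (0.066), Meox1 (0.051) and Pdgfra (0.2) were not. The smallest edgeR adjusted p there was that of Slc17a7 (0.0062), itself a neuron marker that enters the covariate. For the fit over 12 libraries 2 of 84 splits gave as many genes (highest other 67), a share under 0.05. That share concerns the count and not the single genes. At an unadjusted p under 0.05 it gave 1983 genes and 8 of 84 splits gave as many (highest other 2813), so by that count chance is not excluded. Over the 9 tumours in 2 groups it gave 0 genes (smallest edgeR adjusted p = 0.068), so all 84 splits had to give as many (highest other 32), which says nothing about chance. At an unadjusted p under 0.05 that fit gave 1536 genes and 8 of 84 splits gave as many (highest other 2353), so chance is not excluded. These fits differ in their calls, and why was not tested.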
